A study of Scophthalmus maximus with 11 samples.

How the data were processed

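Brain DNA of turbot (Scophthalmus maximus), a flatfish, was profiled by reduced-representation bisulfite sequencing (RRBS) in 11 samples: 3 at 13 days post-fertilization (dpf), 4 at 21 dpf and 4 at 44 dpf. In RRBS the DNA is digested with MspI at CCGG sites, and bisulfite turns unmethylated cytosines into bases read as T. Groups and replicate numbers were taken from the sample titles. The titles do not say that replicates were separate fish or pools, so p-values measure only the spread between these samples, which may be technical.

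Per the submitters' processing notes, the reads were handled with BSMAP 2.90. Per the file headers, each deposited table lists, for each covered cytosine in CpG, CHG or CHH context (H is A, C or T), the count of reads that kept C and the count of reads with C or T. The tables also hold an estimated count, deposited as an effective read count that is scaled by the share of G on the opposite strand, and a methylation fraction made by the authors as C reads over that effective count. The counts were not normalized. Trimming, duplicate removal and the genome build are not given in the sources used here. The only reference table used here comes from assembly ASM2237912v1. On 2 of 22 chromosomes its last gene ended more than 0.5 Mb past the last cytosine in the files, by up to 6.31 Mb. Shared CpGs within 250 bp of a gene end of that table had a mean level of 43.1%, against 44.0% at 4 to 5 kb. Positions were therefore not joined to genes, and regions are named by chromosome, start and end as the files count them, on a build that is not given in the sources used here. Promoters, gene bodies, genomic features and the 16 gene lists fixed beforehand were not analysed here.

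The fit used the C and total read counts. Both strands of a CpG were added. CpGs were kept with 10 or more reads in each library, at or below the 99.9th percentile of coverage of each library, and without a C-to-T variant (5 or more opposite-strand reads with under 80% G). Of 2450879 CpGs covered in at least 1 library, 195398 had 10 reads in each. The variant filter removed 1133 and the coverage limit 2387, which left 191878 shared CpGs. Tiles of 100 bp with 2 or more shared CpGs numbered 42474 and held 156905 CpGs, with a median of 3 CpGs and 255 reads per tile and library. Only 479749 CpGs had enough opposite-strand reads to judge a variant, so variants can remain elsewhere.

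Tiles and single CpGs were tested with a quasi-binomial logistic model over the 11 libraries, with the dispersion moderated as in limma's squeezeVar (limma 3.58.1) and not below 1, and an F test with Benjamini-Hochberg adjustment. A unit was called at an adjusted p below 0.05 and a difference of at least 10 percentage points between stage means. Levels over all shared CpGs and in CHG and CHH context were compared with two-sided exact permutation tests, which cannot go below 0.0286 in these group sizes. The rule for naming, set before the data were examined, named up to 8 genes per direction. It took those with the largest difference among called tiles without overlap between the libraries of both stages. Its parts on genes and gene lists could not be used without an annotation of the build. In their place, up to 8 tiles per direction were named by coordinates with the same ranking. Alternatives fixed beforehand were the coverage minimum, tile width, variant filter, coverage limit, denominator, model, test, minimum difference, a replicate block and leaving out each library. The programs were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16; edgeR was an alternative test.

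The code was tested on simulated data for the same 42474 tiles, of which 200 were changed. With near-binomial spread it called 62, 61 and 50 of 67 tiles changed by 20 points (21 vs 13, 44 vs 21 and 44 vs 13 dpf) and all 67 changed by 40. With the spread of the real libraries it called 0 of 67 at 20 points in each comparison. At 60 points it called 10, 7 and 1 of 66. Among 42274 unchanged tiles it then called 6, 1 and 0, and 15, 2 and 3 with the spread of the wide-coverage libraries. At an unadjusted p below 0.05 stood 11.4%, 8.20% and 8.88% of the unchanged tiles, so unadjusted p-values were too small on average. A low number of calls is therefore no evidence of few changes.

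After the data were examined, the libraries were parted by the number of CpG cytosines covered, at 1900000. The 4 wide-coverage libraries were 13 dpf replicate 1 and 44 dpf replicates 1, 2 and 4. The other 7 are called narrow-coverage libraries. The labels give no batch, and all of 21 dpf lies in the narrow set. The same libraries had first been parted by their CHH level; coverage was then used because that level is itself reported. Fits with the set as a term, fits within each set, counts scaled to the effective depth of each library, and the choice of tiles in one set for reading in the other were all added after the data were examined. Intervals from read counts cover counting error only, since PCR copies are not independent molecules.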

Results

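DNA methylation was measured by RRBS in turbot brain at 13 dpf (n = 3), 21 dpf (n = 4) and 44 dpf (n = 4). The series sets out to profile the brain before, at the climax of and after metamorphosis, the change from a symmetric larva to a flatfish. The labels give ages, which are used here. Libraries covered 1237700 to 2272083 CpG cytosines with a mean of 21.96 to 87.9 reads each. The 4 wide-coverage libraries (13 dpf replicate 1, 44 dpf replicates 1, 2 and 4) covered at least 2024005, and the 7 narrow-coverage libraries at most 1715707. All 4 libraries of 21 dpf were narrow. CpGs of mid level were those with a mean of 30 to 70% in the wide-coverage libraries other than the one scored. Of these, 24.0 to 47.1% were read as 0 or 100% in the narrow libraries and 5.52 to 11.5% in the wide ones. Levels of the shared CpGs correlated at 0.911 to 0.931 between wide libraries and at 0.782 to 0.846 between narrow ones. These correlations are across CpGs, which are not independent replicates.

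The comparison of 21 with 13 dpf asks which regions differ between the youngest larvae and the next stage. Of 42474 tiles, 12 were higher and 2 lower at 21 dpf. On chromosome 13, the tile from 20136601 to 20136700 rose from 72.4% ± 7.24 (SD, n = 3) to 99.92% ± 0.153 (SD, n = 4; 120 to 327 reads per library; adjusted p = 0.00947) and stood at 99.6% ± 0.769 at 44 dpf. Another tile of that chromosome, from 7250501 to 7250600, rose from 66.4% ± 5.15 to 99.94% ± 0.128 (72 to 395 reads; adjusted p = 0.00947). On chromosome 6, the tile from 22204901 to 22205000 rose from 59.7% ± 7.62 to 99.6% ± 0.416 (141 to 821 reads; adjusted p = 0.00947).

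The largest rise, 76.8 percentage points, was on chromosome 11 from 21683201 to 21683300, from 23.1% ± 22.97 to 99.91% ± 0.185 (adjusted p = 0.0290). On chromosome 21, the tile from 2307001 to 2307100 rose from 12.5% ± 10.9 to 77.9% ± 15.5 (adjusted p = 0.0342). The other named tiles that rose lay on chromosome 17 at 8049401 (from 55.5% to 100%), chromosome 11 at 10649501 (from 67.9% to 99.8%) and chromosome 8 at 8122801 (from 68.8% to 100%). The tiles that fell lay on chromosome 13 at 10187101, from 34.0% ± 15.4 to 0%, and on chromosome 10 at 12740901, from 15.6% ± 6.37 to 0%. By counting error alone, these zeros, of 541 and 1220 pooled reads, allow levels of up to 0.555% and 0.246%. PCR copies are not independent molecules, so the levels may be higher. Of the 14 called tiles, 13 had a 21 dpf mean above 99% or below 1%, against 33.1% of all tiles. In the fit, a stage with all its libraries at 0 or 100% adds nothing to the estimated spread, which can favour calls there. The call on chromosome 13 at 20136601 held in all 11 fits that left out 1 library, those at 7250501 and on chromosome 6 in 10, and the other 11 calls in 3 to 7, with 3 for chromosome 21 at 2307001, chromosome 17 at 8049401 and chromosome 13 at 10187101.

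At an unadjusted p below 0.05 stood 5723 tiles (13.5%), against 11.4% of unchanged tiles in simulation, where 6 such tiles were called, or 15 with the spread of the wide-coverage libraries, so false calls could be as many as the 14. The count was 157 without 13 dpf replicate 1, 201 without replicate 2, 7, 4, 8 and 8 without 21 dpf replicates 1, 2, 3 and 4, and 8 without 44 dpf replicate 1. It was 24 within the narrow-coverage libraries and 0 with edgeR (1418 tiles at an unadjusted p below 0.05), with counts scaled to effective depth (455) or with only these 2 stages in the fit (4406). The lean to higher tiles was weaker where more were called: 172 higher and 98 lower with 10 reads in at least 3 libraries of each stage, 106 and 77 with the library set as a term, and 325 and 219 with a replicate block.

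The comparison of 44 with 21 dpf asks which regions differ between the middle stage and the oldest fish. There were 3 higher and 6 lower tiles at 44 dpf. On chromosome 8, the tile from 19690501 to 19690600 fell from 99.7% ± 0.368 (n = 4) to 68.5% ± 7.59 (n = 4; 78 to 340 reads; adjusted p = 0.00922), having been at 83.8% ± 2.42 at 13 dpf. The tile of chromosome 21 from 2307001 to 2307100, which had risen at 21 dpf, fell to 18.02% ± 2.39 (adjusted p = 0.0324). The tile of chromosome 8 from 8122801 to 8122900 likewise fell from 100% to 72.0% ± 8.18 (adjusted p = 0.0324).

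Tiles at 100% at both earlier ages fell on chromosome 20 at 20007501 (to 63.8% ± 13.5), chromosome 18 at 21015801 (to 87.5% ± 4.51) and chromosome 14 at 18870401 (to 87.7% ± 6.11). On chromosome 17, the tile from 14030901 to 14031000 rose from 0% to 15.02% ± 3.21 (adjusted p = 0.0268). By counting error alone, the 503 reads at 21 dpf allow a level of up to 0.596%. The 447 at 13 dpf, also all unmethylated, allow up to 0.671%. Both limits treat reads as independent molecules, so the levels may be higher. The tiles of chromosome 5 at 25874301 and chromosome 20 at 19163901 rose from 0% to 16.8% ± 5.15 and 12.8% ± 0.857. The 21 dpf mean was above 99% or below 1% in 8 of the 9 tiles. Stages with all libraries at 0 or 100% add nothing to the estimated spread, which can favour such calls. Of the 9 tiles, 3 had also been called between 13 and 21 dpf, a comparison that shares the 21 dpf libraries. The call on chromosome 8 at 19690501 held in all 11 fits that left out 1 library, and the other 8 calls in 3 to 7.

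At an unadjusted p below 0.05 stood 4846 tiles (11.4%), against 8.20% of unchanged tiles in simulation. The count was 4, 14 and 4 without 13 dpf replicates 1, 2 and 3, 2, 5 and 1 without 21 dpf replicates 1, 2 and 3, and 16, 31 and 29 without 44 dpf replicates 2, 3 and 4. It was 0 with edgeR (1861 tiles at an unadjusted p below 0.05), with counts scaled to effective depth (583) or in tiles of 500 bp (4114), 1 with only these 2 stages in the fit, and 612 within the narrow-coverage libraries, where 44 dpf is 1 library assumed to vary like the others. With 10 reads in at least 3 libraries of each stage 42 were higher and 139 lower, but within the narrow-coverage libraries 340 were higher and 272 lower.

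**Figure D1:**
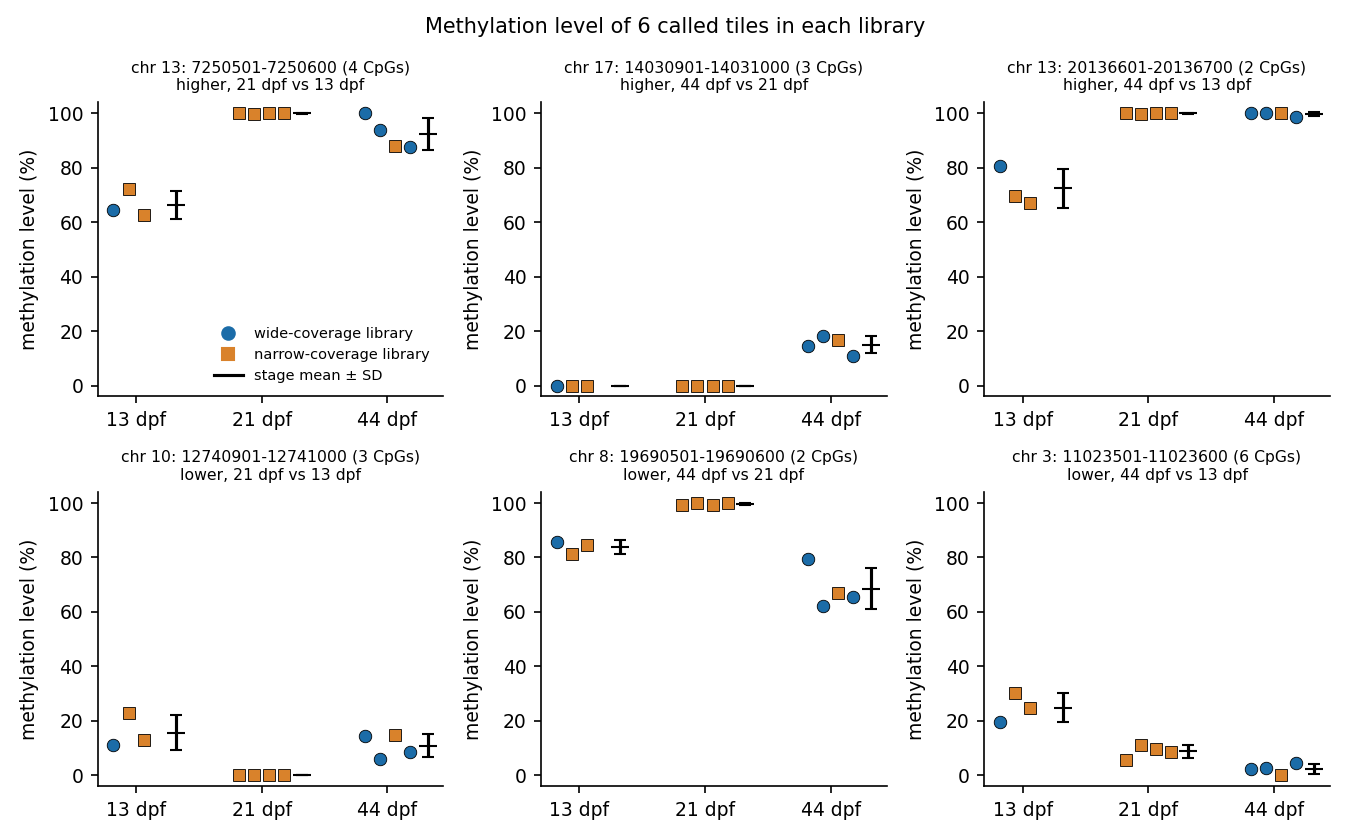
Methylation level (y axis, %) in each library by stage (x axis) for the called tile with the smallest p in each direction of each comparison. Points are libraries, in circles for wide and squares for narrow coverage, and bars are stage means ± SD. The 21 dpf libraries lie at or near 0 or 100% in 5 of the 6 tiles, and the tile of chromosome 3 fell from 24.9% to 8.78% and 2.40%.

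The comparison of 44 with 13 dpf spans the whole series. It gave 3 higher and 2 lower tiles. On chromosome 3, the tile from 11023501 to 11023600, with 6 CpGs, fell from 24.9% ± 5.27 at 13 dpf (n = 3) to 2.40% ± 1.84 at 44 dpf (n = 4; 247 to 1107 reads; adjusted p = 0.0288) and stood between at 21 dpf, at 8.78% ± 2.33 (n = 4). Near the start of that chromosome, the tile from 62401 to 62500 fell from 77.7% ± 1.91 to 65.2% ± 2.19 (717 to 2326 reads; adjusted p = 0.0308), with 69.1% ± 0.686 at 21 dpf. On chromosome 15, the tile from 19948901 to 19949000, with 8 CpGs, rose from 1.29% ± 1.27 to 18.4% ± 4.38 (464 to 2721 reads; adjusted p = 0.0324), with 13.2% ± 3.66 at 21 dpf. The tiles of chromosome 17 at 14030901 and chromosome 13 at 20136601 also rose (both with adjusted p = 0.0288). The 5 calls held in 4 to 6 of the 11 fits that left out 1 library.

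At an unadjusted p below 0.05 stood 5414 tiles (12.7%), against 8.88% of unchanged tiles in simulation. The count was 46, 0 and 2 without 13 dpf replicates 1, 2 and 3, 10, 10 and 0 without 21 dpf replicates 1, 2 and 3, and 0, 0, 14 and 17 without 44 dpf replicates 1, 2, 3 and 4. It was 0 with edgeR (1251 tiles at an unadjusted p below 0.05), with counts scaled to effective depth (751), in tiles of 500 bp (4574) and within the wide-coverage libraries (3786), and 545 within the narrow ones (326 higher, 219 lower), where 44 dpf is 1 library. With 10 reads in at least 3 libraries of each stage 15 were higher and 33 lower, and with only these 2 stages in the fit 0 were higher and 4 lower, none of them among the 5.

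Tiles chosen as lower at 44 dpf in one library set were on average also lower in the other. The choice was made after the data were examined, in the wide-coverage libraries alone: 821 tiles were lower at 44 dpf by at least 30 points on average, with a gap of at least 20 between 13 dpf replicate 1 and each of the 3 others. In the narrow-coverage libraries, which played no part in the choice, these tiles stood at 61.7% at 13 dpf, 51.4% at 21 dpf and 39.8% at 44 dpf. The change of -21.8 points (SE 1.20 over tiles) went with age in an exact one-sided permutation test of stage order over 105 assignments (p = 0.00952, the smallest they can give), and 69.2% of the tiles fell. The 437 tiles higher at 44 dpf in the wide set stood at 63.7%, 68.1% and 65.8% in the narrow set, a change of 2.09 points (exact one-sided p = 0.171). Unchosen tiles of like level changed by -4.41 points for the lower and -4.23 for the higher tiles, so both kinds moved in the direction of the choice relative to these.

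Among the 821 tiles, 324 had each 13 dpf library above each 44 dpf library. The widest fall was on chromosome 4 from 11900901 to 11901000, at 100%, 84.1% ± 15.5 and 22.04% ± 16.4. Next came chromosome 20 from 7139901 to 7140000, at 91.3% ± 15.1, 80.7% ± 13.2 and 15.4% ± 18.4, and chromosome 1 from 10286401 to 10286500, at 94.9% ± 8.82, 78.0% ± 44.0 and 19.3% ± 22.5. Among the 437 higher tiles, 81 had each 13 dpf library below each 44 dpf library, led by chromosome 11 at 21683201 and by chromosome 17 from 7606601 to 7606700, at 13.8% ± 13.9, 69.9% ± 10.5 and 77.6% ± 18.4. These tiles were ranked by their difference and have no test of their own. Wide 13 dpf and narrow 44 dpf are 1 library each.

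**Figure D2:**
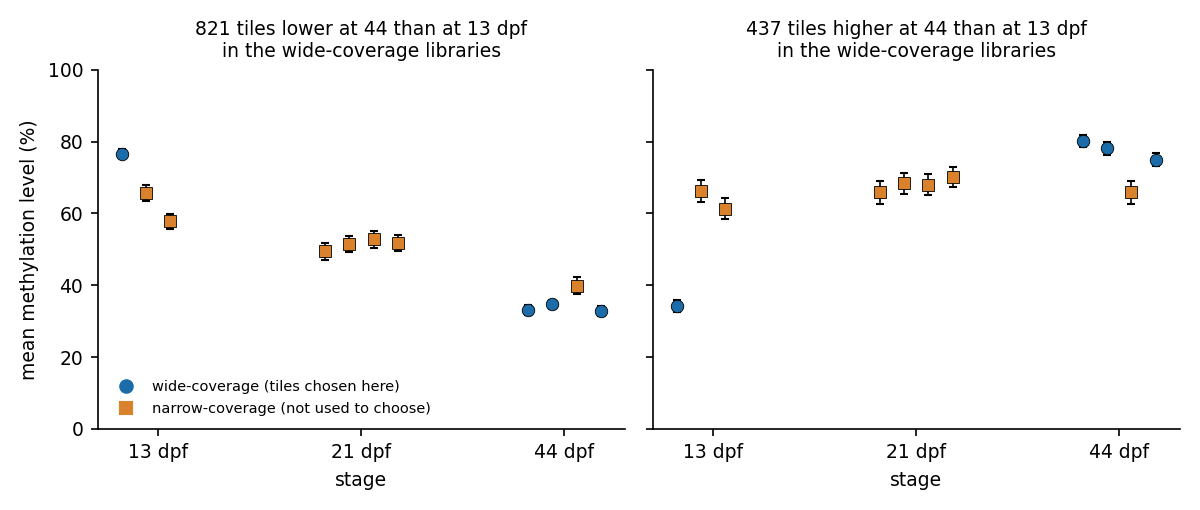
Mean methylation level (y axis, %) of each library by stage (x axis) over the 821 tiles lower (left) and the 437 tiles higher (right) at 44 dpf in the wide-coverage libraries. Circles are wide and squares narrow coverage, and bars are 95% intervals over tiles. In the narrow libraries, not used for the choice, the left tiles run from 61.7% to 39.8% and the right tiles from 63.7% to 65.8%.

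Over the 191878 shared CpGs the mean level was 44.9% ± 0.919 at 13 dpf, 44.6% ± 0.404 at 21 dpf and 43.7% ± 0.641 at 44 dpf. The differences of -0.283 (exact permutation p = 0.686), -0.906 (p = 0.0857, exact) and -1.19 points (p = 0.171, exact; 44 vs 13 dpf) did not pass the test. The change from 13 to 44 dpf was -0.885 within the wide-coverage libraries and -1.66 within the narrow ones. Weighted by coverage, the differences from 13 dpf turned to 3.98 at 21 dpf and 0.836 at 44 dpf, and without 13 dpf replicate 2 the first turned to 0.214. The share of CpGs above 80% was 36.9% ± 0.213 at 21 dpf and 33.7% ± 1.76 at 44 dpf (exact permutation p = 0.0286, the smallest possible; 0.0857 adjusted over the 3 comparisons), but within the narrow libraries it differed by only -0.643 points.

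Single CpGs gave 107 calls at 21 against 13 dpf (76 higher, 31 lower), 35 at 44 against 21 dpf (8 higher, 27 lower) and 42 at 44 against 13 dpf (18 higher, 24 lower). These counts ranged from 0 to 2004, 0 to 655 and 1 to 404 when 1 library was left out. The highest counts came without 13 dpf replicate 2, 44 dpf replicate 3 and 13 dpf replicate 1, and the lowest without 21 dpf replicates 4, 1 or 3, and 3.

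Non-CpG levels were low and differed by library set. The same libraries had first been parted by their CHH level, so this difference is no independent result. CHH levels were 0.723% ± 0.404 at 13 dpf, 1.05% ± 0.0829 at 21 dpf and 0.529% ± 0.397 at 44 dpf, with differences of 0.327 (exact permutation p = 0.0571), -0.521 (p = 0.114, exact) and -0.194 points (p = 0.543, exact). Within the narrow libraries the rise to 21 dpf was only 0.0945 points. The drop to 44 dpf turned within sets, to 0.0716 points in the wide and 0.169 in the narrow libraries against 13 dpf, and to 0.0748 in the narrow ones against 21 dpf. CHG levels moved likewise, from 0.751% ± 0.413 to 1.06% ± 0.0837 and 0.519% ± 0.382. Methylated and incompletely converted cytosines cannot be separated in these reads.

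**Figure D3:**
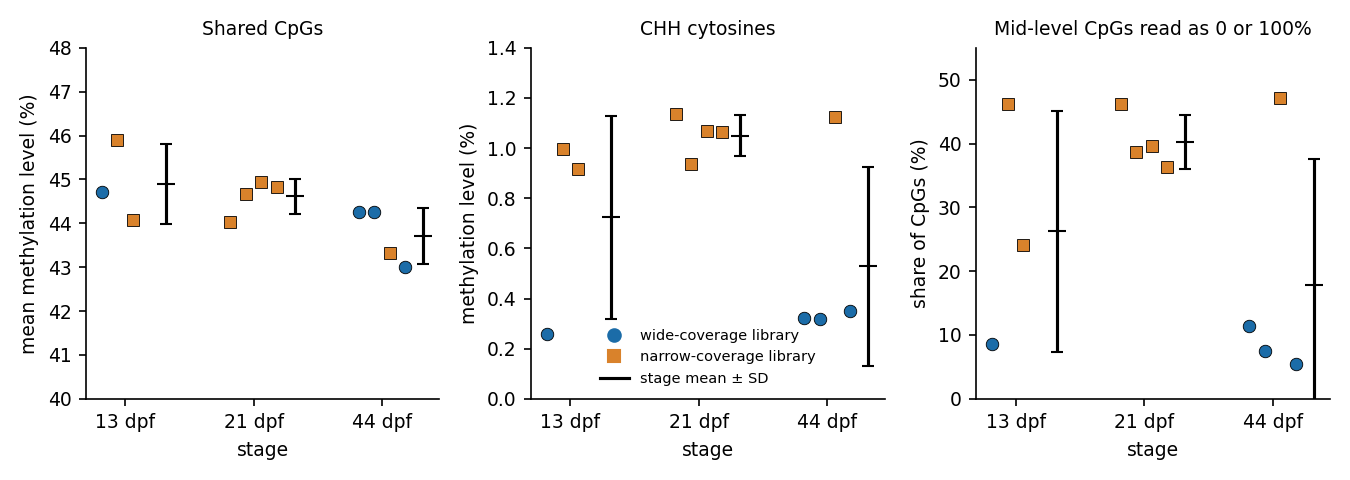
Mean level of shared CpGs (left), CHH level (middle) and share of mid-level CpGs read as 0 or 100% (right), each in % on the y axis, by stage on the x axis. Points are libraries, in circles for wide and squares for narrow coverage, and bars are stage means ± SD. The CHH level and the share differ by set more than by stage. CHH is 0.259 to 0.352% in the wide and 0.916 to 1.13% in the narrow libraries, which had first been parted by that level.

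To compare successive changes without sharing libraries, the change from 13 dpf used 21 dpf replicates 1 and 2, and the change to 44 dpf used replicates 3 and 4. Over 18850 tiles with a mean between 10 and 90% the changes had a covariance of 16.4 squared points, against -0.550 in simulation without effects (SD 2.34 over 20 simulations). The correlation across tiles, which are not independent replicates, was 0.0497. The changes had opposite signs in 48.2 to 49.6% of tiles over the 6 possible splits, against 50.1 to 50.4% in simulation. Without the split, the shared 21 dpf libraries gave a covariance of -94.1, against -122 in simulation.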

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

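The tests of stage alone for the scatter, of the tile splits and of the tiles chosen as lower in the wide set were chosen after the result was seen. Those of read number, molecule number and the CpG splits were set before. In 11 of 60 groups of 4 libraries, 1 library stood apart from the other 3, where chance gives about 3 if the groups are independent and not at a limit. Here 4 are linked measures of 1 library, and in 6 the other 3 libraries had the same value. The library was 44 dpf replicate 3, the only narrow-coverage library of its stage, for its CHG level (1.09%), its CHH level (1.12%), its share of shared CpGs below 10% (47.9%) and its share of mid-level CpGs read as 0 or 100% (47.1%). In called tiles, 1 library stood apart by under 2 points from the other 3. At 21 dpf this was 99.6% in replicate 3 on chromosome 11 at 21683201, 99.7% in replicate 2 on chromosome 13 at 7250501, 99.7% in replicate 2 on chromosome 13 at 20136601, 99.86% in replicate 3 on chromosome 14 at 14310101, 99.3% in replicate 4 on chromosome 22 at 71101 and 68.1% in replicate 1 on chromosome 3 at 62401. At 44 dpf it was 98.5% in replicate 4 on chromosome 13 at 20136601. Outside the CpG comparisons, 569 of 72829 cytosines had a mixed base on the opposite strand, and 512 of 359147 shared non-CpG cytosines had a mean level of 15% or more.

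The narrow-coverage libraries scattered widely at CpGs of mid level. Scatter was measured around the mean of the wide-coverage libraries other than the one scored, so real differences between the sets count as scatter too. Too few reads were not the whole cause: the scatter shrank with depth, from 1.25 to 1.31 effective independent reads at 10 to under 30 reads to 2.94 to 3.53 at 100 to under 300, but the wide libraries reached 5.91 to 9.58 at that same depth. Stage alone was not the cause either, since within 13 dpf the narrow libraries read at least 2.80 times as many mid-level CpGs as 0 or 100% as the wide one. A candidate explanation is that few DNA molecules lay behind the reads, as at that depth at least 16.6% of mid-level CpGs were still read as 0 or 100% in each narrow library, against at most 2.53% in the wide ones. A biological difference between these fish stays open and was not tested.

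When the called regions were set against other splits of the same libraries, for 21 against 13 dpf 1 of 35 splits, the real one, gave 14 tiles, and the highest other gave 7; for CpGs the real split gave 107 and the highest other 106. A share of 1 in 35 (0.0286) is the smallest these splits can give and is not adjusted over the 3 comparisons. Without 1 library the counts ranged from 4 to 201 tiles and 0 to 2004 CpGs. In simulation with the spread of the wide-coverage libraries, 15 unchanged tiles were called. Chance is therefore not excluded for 21 against 13 dpf. For 44 against 21 dpf chance is not excluded, with 2 of 35 splits giving as many as the real 9 tiles (highest other 11) and 4 giving as many as the real 35 CpGs (highest other 85). For 44 against 13 dpf it is not excluded either, with 4 of 35 splits giving as many as the real 5 tiles (highest other 19) and 7 as many as the real 42 CpGs (highest other 498). The split of wide against narrow libraries gave 19 tiles and 443 CpGs, and that of 13 dpf with 44 dpf replicate 3 gave 19 and 498, which points to a structure of the samples other than age.

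The 821 tiles chosen as lower at 44 dpf in the wide set fell by a mean of 21.8 points in the narrow set, where 69.2% fell and 27.8% rose. Tiles of like level that were not chosen changed by -4.41 points, which argues against a general drop or a return toward the mean as the whole cause. They were matched on the mean level in the wide set alone, not on the spread between libraries. A larger drop in tiles that vary more is therefore not excluded. The change was -22.1 points at CpGs with enough opposite-strand reads in at least 1 library and no variant found. This does not exclude C-to-T variants in libraries without such reads, which can include 44 dpf replicate 3. Unequal conversion was not the cause, since the CHH level was 0.169 points higher in the 44 dpf library. A loss of methylation with age in these regions may account for the fall, as a hypothesis, and a difference in cell makeup or parentage stays open and untested. The narrow 44 dpf value rests on replicate 3 alone, which also had the least similar variants (median correlation of base shares with other libraries 0.346, against 0.521 to 0.686 for the rest).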

How the results depend on the processing

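The library sets, effective depth, the choice of tiles in one set for the other and both kinds of shuffle were chosen after the data were examined; the other alternatives were fixed before. Counts are given for 21 vs 13, 44 vs 21 and 44 vs 13 dpf, and where nothing else is said the cause was not tested. The 14, 9 and 5 called tiles became 270, 181 and 48 with 10 reads in at least 3 libraries of each stage (95645 tiles tested, with some libraries missing; the effects of these were not separated), 9, 4 and 1 at 25 points, 6, 1 and 0 with each tile's own dispersion, and 544, 571 and 443 with a replicate block. In tiles of 500 bp the last 2 counts were 0 and 0, and with only the 2 stages compared the counts were 0, 1 and 4, the 4 being none of the 5 called before (adjusted p of those 0.0665 to 0.0994). With the library set as a term they were 183, 224 and 213; stages shuffled within sets 12 times gave up to 129, 269 and 183, so much of this comes from the fit. Counts were 0, 0 and 0 when scaled to effective depth and 0, 0 and 0 with edgeR, 24, 612 and 545 within the narrow set, 0 within the wide set (44 vs 13 dpf), and 8860, 8092 and 8701 with Fisher's exact test on pooled reads, which ignores the spread between libraries. Leaving out 1 library gave 4 to 201, 1 to 31 and 0 to 46 tiles. The 107, 35 and 42 CpGs became 243 and 107 (first 2) with a minimum of 5 reads, 23 (last) at 25 points, 6145, 6993 and 4858 with the replicate block, 50303, 46644 and 46722 with Fisher's test, and 0 to 2004, 0 to 655 and 1 to 404 without 1 library. No pairing by replicate number was detected. Same-numbered libraries correlated at -0.015 to 0.0308 in their deviations, and other pairs of libraries from different stages at -0.0361 to 0.0362. Shuffled numbers gave a median of 370 tiles over 12 shuffles (44 vs 13 dpf), and 1 gave as many as the real 443. The block fit may thus call tiles whatever the numbers. The mean CpG level at 21 vs 13 dpf reversed to 3.98 weighted by coverage, to 1.08 over all CpGs of each library and to 0.214 without 13 dpf replicate 2, and at 44 vs 13 dpf to 0.836 weighted by coverage; without 1 library it ranged from -0.692 to 0.214, -1.10 to -0.670 and -1.60 to -0.691. CHG differences reversed within the narrow set to 0.0341 (44 vs 21 dpf) and 0.103 (44 vs 13 dpf) and within the wide set to 0.0516, and CHH differences to 0.0748, 0.169 and 0.0716. The covariance of successive changes reversed to -94.1 without the split, where shared libraries set the sign, and was 15.3 to 17.4 in the other splits. Tiles chosen anew under each of 7 alternatives (413 to 1797 lower, 177 to 1151 higher, in place of 821 and 437) changed by -18.5 to -25.4 points (p = 0.00952 each, exact test) and by 1.54 to 5.55. Of 673 values of called tiles under alternatives, 390 stayed past the threshold, 283 did not and 0 reversed. A reversal was hardly possible, since many alternatives reuse the same levels and nearly all called tiles had no overlap between the stages. Of 28 calls, 2 held in all 11 fits that left out 1 library. Analyses of promoters, gene bodies, features and gene lists were not run. The spread between libraries limits the rest. Changes of 20 points were called in 0 of 67 simulated tiles in each comparison with that spread, in which real stage and set differences also count. With near-binomial spread at the same depth, 62, 61 and 50 of 67 were called.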

Other observations

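The choice of tiles described here, the 400 to 2000 bp window and the counts of pairs were set after the data were examined; the 1 kb test was written before its result. The 821 tiles chosen as lower at 44 dpf lay on each of the 22 chromosomes, in numbers that did not differ detectably from each one's share of tiles (chi-square p = 0.169). They held fewer CpGs than unchosen tiles of like level (a mean of 2.95 against 3.28). This was not particular to them, as the tiles chosen as higher held a mean of 2.85. The choice in the other direction gave a smaller change: 2639 tiles lower at 44 dpf in the narrow libraries changed by -8.17 points in the wide ones, and 1275 higher tiles by 2.21. Choosing tiles in which 44 dpf replicate 1, 2 or 4 was the odd wide library instead gave narrow-set changes from -11.5 to 7.32 points. The change of -21.8 lies outside that range. Each of these choices also set the odd library apart from 13 dpf replicate 1, so the range is not free of a contrast of ages.

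Whether the loss may reach beyond the chosen tiles was tested in unchosen tiles nearby, with a result that depends on the distance. Within 1 kb, 226 such tiles changed by -9.41 points (SE 1.898) in the narrow libraries, against -3.01 for tiles of like level farther off, which meets the bound set for a wider loss only with a standard error over tiles. The 44 dpf value there is 1 library and neighbouring tiles are not replicates, so a wider loss stays open. Since a single RRBS fragment, whose length was not measured here, can span adjacent tiles, 195 tiles at 400 to 2000 bp were then tested, and they changed by -5.66 points (SE 1.70) against -1.89, which decides neither way. Pairs of chosen tiles also differed by distance. Within 1 kb there were 45, against a median of 23 in 1000 random draws of tiles of like level, of which 5 had as many. At 400 to 2000 bp there were 9, fewer than the median of 20, with 24 draws at or below.

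Non-CpG levels were higher in tiles with a CpG level above 80% than in tiles below 10%. Among cytosines followed by A or T, the excess ranged from 0.0423 to 0.212 percentage points over the 11 libraries, and exceeded that of cytosines followed by C in 10 of them.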
